A study of Mus musculus with 15 samples.

How the data were processed

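Kidney messenger RNA from wild-type mice was measured by RNA sequencing in 15 samples, which the labels place in 3 groups of 5: vehicle, L-alanine (L-ala) and D-alanine (D-ala), each with a time of 2 h. Doses, routes and the make-up of the vehicle are not given in the sources used here, so no claim of matched doses is made. Replicate numbers follow the order of the samples within a group, pair no samples and carry no other meaning. The labels do not say that the samples came from separate animals, so every p-value here measures the spread between these samples, part of which may be technical. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded messenger RNA kit from the TruSeq line. Per the submitters' processing notes, TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and the mouse build mm10 were used, in roles and an order that the notes do not state. The program that made the values per gene, its annotation and whether it used strand are not given in the sources used here, so reads of overlapping genes, antisense partners and near-identical paralogs such as Lyz1 and Lyz2 could have been divided between them.

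One deposited table held 23284 genes with 3 columns per library. The deposited FPKM values, named so per the file headers, are fragment counts scaled to transcript length and library depth and were the values tested. Of the deposited genes, 5217 were at 0 FPKM in every library. The second column holds log2 values, headed as processed signal per the file headers; over the 10664 genes at 1 FPKM or more in every library it lay within 0.0012 of the log2 FPKM centred on each gene's mean, and it was not used further. The third column is headed as a count per the file headers, but it was treated as a score on a common scale, because the deposited numbers were whole counts multiplied by a factor per library and rounded again. Gaps in the low whole numbers gave that factor for each library, and 86.82% of the low values came within 0.1 of a whole number after division. The recovered depth ran from 7.55 M reads in vehicle replicate 1 to 10.9 M in L-ala replicate 1. Because the numbers are rescaled, no count model was fitted to them, and the branch of the design fixed for normalized values was used. FPKM carry no counting interval of their own, so precision is given as the spread between libraries.

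Genes with at least 1 FPKM in 5 or more libraries were tested, 11781 in all, and 11503 were not. Values were taken as log2(FPKM + 1), and fold changes are on that scale, which understates the change of low genes. A linear model with 1 mean per group was fitted to all 15 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation that used the mean-variance trend and was robust to outlying variances. The 3 comparisons were D-ala against vehicle, L-ala against vehicle and D-ala against L-ala, and a change was called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Every adjusted p in the text comes from limma, and intervals are at 95%. Values of single measures per library were compared with exact two-sided permutation tests. Their p-values were not adjusted for the number of measures or comparisons, so some under 0.05 can arise by chance. Gene lists were tested with limma's camera with the correlation between genes preset to 0.01, adjusted over the lists within a comparison, and again with a correlation estimated from the data. Of 43 lists of pathway genes and cell type markers, with 643 members in the table, 40 had at least 5 tested members. Members were also counted with p-values adjusted over the list alone. Of the list calls, 1 of 21 for D-ala against vehicle, 0 of 13 for L-ala against vehicle and 0 of 6 for D-ala against L-ala held with an estimated correlation. With limma's fry, a directional test of each list by itself, 16, 12 and 5 of the 40 lists passed in the same comparisons. A list can pass fry without standing out from the other genes, so the tests answer different questions.

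The groups, tests, filters, gene lists, the rule for named genes and the alternatives listed first below were chosen before the data were examined. Named genes were the 8 largest rises and the 8 largest falls per comparison among called genes with a mean of at least 1 FPKM in 1 of the groups and no overlap between the groups' libraries, leaving out Gm and Rik gene models. To these were added up to 3 called members of each list by smallest p, and always Per1, Per2, Arntl, Nr1d1, Dbp, Pck1, G6pc, Fbp1 and Dao. A gene named in one comparison may be given in the others. Coordinates are those of GENCODE M21 on GRCm38, the assembly behind mm10, and 20911 gene symbols of the table matched directly, 1911 as older symbols and 462 not at all. Gene length was taken as the scaled count per FPKM, and GC content from the longest protein-coding transcript, which 11639 of the 11781 tested genes had.

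Alternatives chosen beforehand were median-of-ratios scaling, quantile normalization, array quality weights, no mean-variance trend, no filter, a mean of at least 5 FPKM, a fit of only the 10 libraries compared, pseudocounts of 0.1 and 5, fold changes kept only from 1.5 up, camera with an estimated correlation, fry's directional test, a split of the vehicle libraries, and each library left out in turn. After the data had been seen, 5 were added: removal of each library's trend with gene length, the same for GC content, limma's voom on the recovered reads, omission of the 3 libraries of lowest recovered depth, and the level of adipocyte markers as a covariate.

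The procedure was tested on simulated data with the real means and spreads. For D-ala against vehicle, with all 11781 genes in the fit, 91.04% of 67 genes changed by 1.5-fold, 97.01% of 67 changed by 2-fold and 100% of 66 changed by 4-fold were called, with 0 calls of the wrong sign and 13 calls among 11581 unchanged genes. For L-ala against vehicle, 1 list raised by 0.5 on the log2 scale passed and 0 of 39 others did, and a simulated length trend that gave 3546 calls gave 0 after removal. The noise was drawn for each gene independently. The simulation therefore does not show how often lists of correlated genes pass camera with the preset correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.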

Results

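Kidney transcripts were measured by RNA sequencing in wild-type mice that had received vehicle, L-alanine or D-alanine, with 5 samples per group at 2 h. The amino acids are mirror-image forms of each other. L-alanine is a building block of proteins and a substrate for glucose production, and D-alanine is degraded by D-amino acid oxidase (Dao), a peroxisomal enzyme that is abundant in the kidney. The series concerns the effect of D-alanine, so the comparison with vehicle asks what D-alanine changed. The comparisons with L-alanine ask which of these changes differed between the 2 treatments. Doses and routes are not given, so such differences cannot be assigned to the mirror form alone. Values are FPKM, given as mean ± SD over the 5 libraries of a group, and log2 fold changes carry their standard errors (SE). The recovered depth was 7.55 to 10.9 M reads per library. Of 23284 genes, 11781 were tested.

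The first principal component of the libraries held 20.5% of the variance and the second 15.9%. L-ala replicate 5 stood apart from its group, with a mean correlation of -0.118 with the other L-ala libraries on gene-centred values and a score of 10.4 on the second component. Expression followed gene length differently in the groups. The Spearman correlation of gene-centred expression with length, across genes, averaged -0.27 ± 0.31 in the L-ala libraries, 0.18 ± 0.20 in the vehicle libraries and 0.12 ± 0.16 in the D-ala libraries (SD, n = 5). Exact two-sided permutation p-values were 0.0397 for L-ala against vehicle, 0.0476 for D-ala against L-ala and 0.603 for D-ala against vehicle. Correlations with GC content averaged 0.10 ± 0.09 under D-ala, -0.10 ± 0.12 under vehicle and 0.01 ± 0.14 under L-ala. For D-ala against vehicle the exact permutation p was 0.0238, for L-ala against vehicle 0.159 and for D-ala against L-ala 0.333. With each library's trend with GC content removed, 1113 of the 1349 genes called for D-ala against vehicle stayed called. Expression of red blood cell markers averaged 4.35 ± 0.39 under L-ala, 3.01 ± 0.83 under vehicle and 3.16 ± 0.68 under D-ala on the log2 scale (exact permutation p = 0.0159 for L-ala against vehicle and 0.0238 for D-ala against L-ala). Neutrophil markers averaged 0.86 ± 0.15 under L-ala, 0.37 ± 0.17 under vehicle and 0.42 ± 0.17 under D-ala (exact permutation p = 0.00794 for L-ala against each other group). The neutrophil list had fewer than 5 tested members, so camera was not run on it. Its means are low and include members whether or not they reached the FPKM filter. Adipocyte markers varied between libraries of one group, from 1.92 to 4.69 under D-ala, and their library means did not pass for D-ala against vehicle (exact permutation p = 0.302). The adipocyte list passed camera, however, for D-ala against vehicle (median 0.82, adjusted p = 0.0291; adjusted p = 0.653 with an estimated correlation) and for D-ala against L-ala (adjusted p = 0.0239; adjusted p = 0.715 with an estimated correlation). Camera lost it for D-ala against vehicle without vehicle replicate 2 (adjusted p = 0.119) or 3 (0.117) or D-ala replicate 1 (0.0661), 2 (0.214) or 3 (0.0630). For D-ala against L-ala it was lost without L-ala replicate 3 (adjusted p = 0.0631) or 5 (0.0522) or D-ala replicate 2 (0.124). No pair of libraries in a group differed by as little as sampling noise gives.

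**Figure D1:**
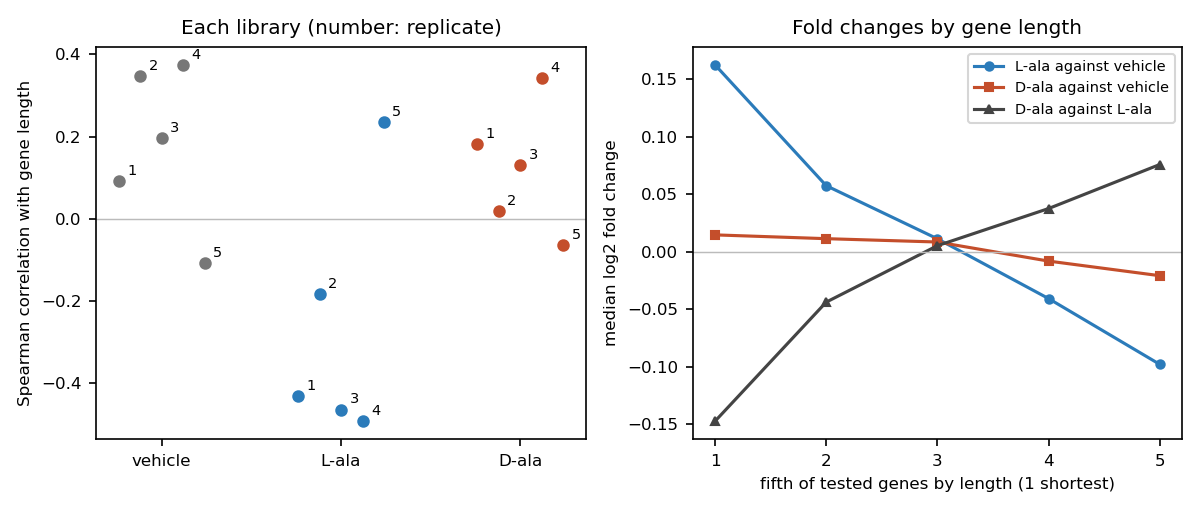
The left panel plots, for each of the 15 libraries (numbered by replicate), the Spearman correlation across genes between gene-centred log2 expression and gene length, and the right panel the median log2 fold change of each comparison in 5 equal bins of the tested genes by length, from the shortest (1) to the longest (5). For L-ala against vehicle the median fell from 0.16 in the shortest bin to -0.10 in the longest, and L-ala replicates 1 to 4 lay below all vehicle libraries while replicate 5 did not.

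D-alanine raised 3 named genes of the core clock list, Bhlhe40, Nfil3 and Per1, and 2 genes of glucose production, G6pc and Pck1, while other genes of the clock list rose, fell or did not pass. Bhlhe40, which codes for a repressor that opposes the clock's activators (GRCm38 chromosome 6, 108660629 to 108666925), rose from 44.6 ± 9.87 FPKM under vehicle to 135 ± 25.1 under D-ala (log2 fold change 1.59, SE 0.15, adjusted p = 9.45e-06). Nfil3, a repressor of clock output genes (chromosome 13, 52967209 to 52981073), rose from 3.41 ± 0.683 to 11.6 ± 3.88 FPKM (1.45, SE 0.22, adjusted p = 7.60e-04). Per1, a core component of the negative limb of the clock (chromosome 11, 69095217 to 69109960), rose from 13.3 ± 7.42 to 34.2 ± 7.67 FPKM (1.42, SE 0.28, adjusted p = 0.00611). G6pc, which releases free glucose from glucose 6-phosphate (chromosome 11, 101367561 to 101377903), rose from 266 ± 51.7 to 458 ± 122 FPKM (0.77, SE 0.18, adjusted p = 0.0142). Pck1, which makes phosphoenolpyruvate from oxaloacetate (chromosome 2, 173153048 to 173159273), rose from 2437 ± 749 to 4136 ± 553 FPKM (0.82, SE 0.18, adjusted p = 0.00989).

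Members of the core clock list moved both ways. Of its 17 tested members, 4 rose, 2 fell and 11 did not pass (6 and 4 adjusted over the list alone). Besides Bhlhe40, Nfil3 and Per1, the member that rose was Gm129 (Ciart), a repressor of the clock's activators, at 12.2 ± 6.39 against 30.1 ± 9.22 FPKM (1.30, SE 0.29, adjusted p = 0.0114). Those that fell were Nr1d2 (-0.41, SE 0.06, adjusted p = 8.00e-04) and Cry1 (-0.43, SE 0.11, adjusted p = 0.0208). Gm129 and Cry1 are outside the rule for named genes and were chosen after their values were seen. Without vehicle replicate 4 or D-ala replicate 2 the members that fell numbered 1. Per2 (0.32, adjusted p = 0.0962), Dbp (-0.30, adjusted p = 0.0663) and Nr1d1 (0.11, adjusted p = 0.701) did not pass; Dbp passed without vehicle replicate 1 (adjusted p = 0.0486), L-ala replicate 3 (0.0311) or D-ala replicate 5 (0.0244). Arntl was too low to test, at 0.418 ± 0.112 FPKM under vehicle and 0.469 ± 0.0978 under D-ala. The list had a median of 0.01 and a mean of 0.30, and camera gave adjusted p = 0.394 (adjusted p = 0.7497 with an estimated correlation). The mean of the list per library was 3.69 ± 0.05 under D-ala and 3.41 ± 0.12 under vehicle on the log2 scale, without overlap (exact permutation p = 0.00794).

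Of 18 tested gluconeogenesis genes, 7 rose, 0 fell and 11 did not pass (11 and 0 adjusted over the list alone). The list had a median of 0.22 and passed camera (adjusted p = 4.15e-06; adjusted p = 0.159 with an estimated correlation). Gpt, the alanine aminotransferase that turns L-alanine into pyruvate, rose (0.53, SE 0.13, adjusted p = 0.0135), as did Slc25a10, a mitochondrial dicarboxylate carrier (0.32, SE 0.07, adjusted p = 0.00924). Fbp1 was at 0.18 (adjusted p = 0.0804) and passed without L-ala replicate 4 (adjusted p = 0.0446). Dao was at 0.19 (95% interval 0.04 to 0.35, adjusted p = 0.0982). The call of G6pc was lost without the 3 libraries of lowest depth (adjusted p = 0.0557, range over its alternatives 0.0104 to 0.0557).

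Immediate early genes, which respond to many stimuli without new protein synthesis, rose together under D-ala. Of 21 tested, 15 rose, 0 fell and 6 did not pass (18 and 0 adjusted over the list alone), with a median of 1.49 (camera adjusted p = 3.91e-16; adjusted p = 0.109 with an estimated correlation). Btg2, an antiproliferative gene, rose from 11.7 ± 4.03 to 95.4 ± 28.2 FPKM (2.94, SE 0.25, adjusted p = 9.45e-06). Junb, a subunit of the AP-1 transcription factor, rose from 18.7 ± 6.01 to 86.4 ± 20.4 FPKM (2.17, SE 0.23, adjusted p = 6.49e-05). Outside the list, Plk3, a stress-responsive kinase, had the largest rise of the named genes in this comparison, from 15.1 ± 18.8 to 204 ± 62.8 FPKM (4.30, SE 0.61, adjusted p = 0.00104). Of 17 tested targets of cAMP and CREB, 10 rose, 0 fell and 7 did not pass (12 and 0 adjusted over the list alone; camera adjusted p = 5.99e-09; adjusted p = 0.0395 with an estimated correlation). Sik1, a kinase induced by cAMP that restrains CREB coactivators, rose from 19.6 ± 7.65 to 82.2 ± 9.45 FPKM (2.08, SE 0.21, adjusted p = 2.98e-05). Under L-ala, 5 of the 17 cAMP and CREB targets rose, 0 fell and 12 did not pass (camera adjusted p = 0.0252, and 0.472 with an estimated correlation). Genes of these lists overlap: Fos, Nr4a1, Nr4a2 and Dusp1 are tested members of both, Nr4a3 is in both but was not tested, and Per1, Pck1 and G6pc are also cAMP targets.

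In the ATF4 list, the response to amino acid shortage and related stresses, 6 of 20 tested members rose, 0 fell and 14 did not pass (6 and 0 adjusted over the list alone; camera adjusted p = 0.00548; adjusted p = 0.224 with an estimated correlation). Atf4 itself rose from 82.7 ± 14.9 to 160 ± 24.2 FPKM (0.95, SE 0.12, adjusted p = 8.83e-05) and Ppp1r15a, a phosphatase subunit that restores translation, rose by a log2 fold change of 0.86 (SE 0.11, adjusted p = 1.26e-04). Of 19 tested glucocorticoid targets, 7 rose, 0 fell and 12 did not pass (7 and 0 adjusted over the list alone; camera adjusted p = 2.10e-05; adjusted p = 0.224 with an estimated correlation). They included Errfi1, an inhibitor of the epidermal growth factor receptor (1.11, SE 0.15, adjusted p = 2.59e-04), and Mt2, a metal-binding protein (0.91, SE 0.18, adjusted p = 0.00454). Among transporters of the alanine handling list, Slc3a2, the heavy chain of several amino acid exchangers, rose (0.67, adjusted p = 0.00244). Slc7a8, one of its light chains, rose too (0.43, adjusted p = 0.00976), and Slc38a2, a sodium-coupled carrier of small neutral amino acids, fell by 0.78 on the log2 scale (adjusted p = 2.51e-04). In that list of 21 tested members 5 rose, 1 fell and 15 did not pass (7 and 2 adjusted over the list alone, camera adjusted p = 0.169). Genes of the ATF4 list rose under L-ala as well, where 5 of 20 rose, 0 fell and 15 did not pass (camera adjusted p = 0.0582). Library means of the ATF4 list were 3.54 ± 0.13 under D-ala, 3.53 ± 0.08 under L-ala and 3.24 ± 0.13 under vehicle. For each isomer against vehicle the exact permutation p was 0.00794, and between the isomers it was 0.849. Of the 20 genes, 2 were higher under D-ala than under L-ala and 0 were lower.

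Interferon-induced and macrophage genes were lower under D-ala. Of 18 tested interferon response genes, 0 rose, 9 fell and 9 did not pass (0 and 11 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 3.05e-06; adjusted p = 0.159 with an estimated correlation). Isg15, a ubiquitin-like antiviral protein, fell from 7.17 ± 1.21 to 4.50 ± 0.616 FPKM (-0.56, SE 0.12, adjusted p = 0.00522). Outside the list, Ifitm1, an interferon-induced membrane protein, fell from 12.7 ± 2.10 to 4.10 ± 2.40 FPKM (-1.54, SE 0.27, adjusted p = 0.00236). Without vehicle replicate 1, 4 or 5 or D-ala replicate 1, the members of the list that fell numbered 5. Of 10 tested macrophage and dendritic markers, 0 rose, 5 fell and 5 did not pass (0 and 7 adjusted over the list alone; camera adjusted p = 2.82e-05; adjusted p = 0.159 with an estimated correlation). The number that fell was 1 without vehicle replicate 1 or 5 or D-ala replicate 2, 2 without D-ala replicate 1 or 4, and 3 without vehicle replicate 4 or D-ala replicate 3. Lyz2, a lysozyme of macrophages and neutrophils, fell from 14.6 ± 1.55 to 7.29 ± 0.936 FPKM (-0.91, SE 0.10, adjusted p = 2.66e-05). Macrophage and dendritic markers went down under L-ala as well, as given with the L-ala comparison. Other marker lists outside the tubule went both ways. Podocyte markers were higher in their library means, at 2.99 ± 0.12 under D-ala and 2.76 ± 0.18 under vehicle on the log2 scale (exact permutation p = 0.0397), but did not pass camera (adjusted p = 0.1275). Adipocyte markers, given above, went up, and markers of smooth muscle and renin cells did not pass camera (adjusted p = 0.372). Endothelial markers are given with the L-ala comparison, and of 9 fibroblast and pericyte markers 0 rose, 2 fell and 7 did not pass (1 and 3 adjusted over the list alone; camera adjusted p = 0.0287; adjusted p = 0.488 with an estimated correlation). For these 9, camera did not pass without vehicle replicate 1 (adjusted p = 0.0940) or D-ala replicate 1 (0.0661). The number that fell was 1 without vehicle replicate 1, 3, 4 or 5 or D-ala replicate 1, 2, 4 or 5, and the number that rose was 1 without vehicle replicate 1, L-ala replicate 5 or D-ala replicate 4.

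In all, 1349 genes changed between D-ala and vehicle, 769 up and 580 down, and 77 of them were up and 8 down by 2-fold or more. At an unadjusted p under 0.05 there were 3126. Groups did not overlap in 1282 tested genes, 932 of them called; chance gives 0.794% of genes. Rises made up 57.0% of the calls, and 46.95% of 1576 calls after quantile normalization. Without vehicle replicate 4 the number of calls was 812. With all libraries, 21 of 40 lists passed camera, 13 up and 8 down.

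**Figure D2:**
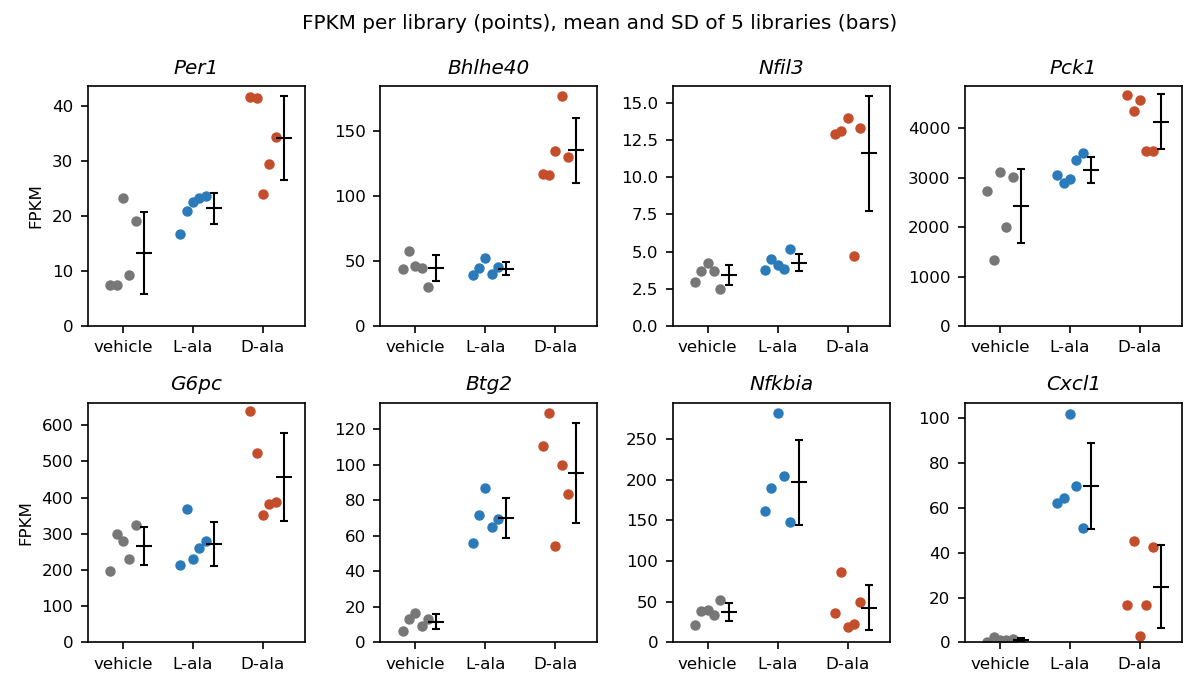
FPKM of 8 genes in each library (points; vehicle, L-ala and D-ala, 5 libraries each) on linear axes that start at 0, with bars for the mean and SD of the group. All D-ala libraries lay above all others for Bhlhe40 (at least 116 FPKM), all L-ala libraries above all others for Nfkbia (at least 148 FPKM) and Cxcl1 (at least 51.0 FPKM), and both treated groups lay above vehicle for Btg2.

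L-alanine raised genes controlled by NF-kB, the transcription factor of inflammation, together with immediate early genes, and D-alanine raised the chemokine Cxcl1 as well. Cxcl1, a chemokine that attracts neutrophils (GRCm38 chromosome 5, 90891241 to 90893115), rose from 1.26 ± 0.782 to 69.9 ± 19.2 FPKM (log2 fold change 4.999, SE 0.57, adjusted p = 9.54e-04). Cxcl1 also rose under D-ala, to 24.9 ± 18.4 FPKM (3.13, SE 0.57, adjusted p = 0.00453), with every D-ala library above every vehicle library. With voom that rise of Cxcl1 did not pass (adjusted p = 0.0945, range over its alternatives 7.59e-05 to 0.0945). Nfkbia, the inhibitor that NF-kB induces as its own brake (chromosome 12, 55489410 to 55492647), rose from 37.4 ± 10.9 to 197 ± 52.3 FPKM (2.38, SE 0.37, adjusted p = 0.00411). Tnfaip3, a ubiquitin-editing enzyme that ends NF-kB signalling (chromosome 10, 19000910 to 19015657), rose from 2.1998 ± 1.27 to 12.8 ± 3.12 FPKM (2.15, SE 0.32, adjusted p = 0.00298). Cxcl2, a chemokine related to Cxcl1, rose by a log2 fold change of 2.10 (SE 0.20, adjusted p = 6.24e-05). Of 17 tested NF-kB targets, 6 rose, 1 fell and 10 did not pass (7 and 1 adjusted over the list alone), with a median of 0.57 (camera adjusted p = 9.85e-04; adjusted p = 0.472 with an estimated correlation). Without vehicle replicate 4 or L-ala replicate 1 or 4, the number that fell was 0; camera lost the list without the 3 libraries of lowest depth (adjusted p = 0.0528). Cell markers moved with these genes. Neutrophil markers were at 0.86 ± 0.15 under L-ala and 0.37 ± 0.17 under vehicle in their library means (exact permutation p = 0.00794), and red blood cell markers at 4.35 ± 0.39 and 3.01 ± 0.83 (exact permutation p = 0.0159). The neutrophil list had too few tested members for camera. Of 7 red blood cell markers 0 rose, 0 fell and 7 did not pass (6 and 0 adjusted over the list alone), with a median of 2.11 (camera adjusted p = 0.01002; adjusted p = 0.472 with an estimated correlation). Camera lost these 7 without L-ala replicate 5 (adjusted p = 0.0678), and 1 rose without vehicle replicate 1 or 2, L-ala replicate 4 or 5 or D-ala replicate 3.

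Of 21 immediate early genes, 16 rose under L-ala, 0 fell and 5 did not pass (16 and 0 adjusted over the list alone), with a median of 1.4965 (camera adjusted p = 1.14e-14; adjusted p = 0.428 with an estimated correlation). Fos, the partner of Jun in AP-1, rose from 2.79 ± 1.95 to 27.003 ± 20.049 FPKM (2.87, SE 0.46, adjusted p = 0.00529). Jun rose from 17.2 ± 3.31 to 98.2 ± 34.6 FPKM (2.40, SE 0.21, adjusted p = 6.24e-05). Glucocorticoid targets rose in 9 of 19 cases, fell in 0 and did not pass in 10 (10 and 0 adjusted over the list alone; camera adjusted p = 2.64e-05; adjusted p = 0.472 with an estimated correlation), among them Errfi1 (0.93, SE 0.15, adjusted p = 0.00364); Nfkbia belongs to this list too. The sodium-coupled carrier Slc38a2 fell by 0.82 on the log2 scale (adjusted p = 8.22e-04). Of 18 gluconeogenesis genes, 5 rose, 0 fell and 13 did not pass (8 and 0 adjusted over the list alone; camera adjusted p = 6.16e-05; adjusted p = 0.472 with an estimated correlation). The number that rose was 1 without vehicle replicate 1 or 4 or L-ala replicate 4, and 3 without vehicle replicate 2 or L-ala replicate 1 or 3. With the trend with gene length removed it was 3. Proximal tubule S1-S2 markers were at 8.12 ± 0.09 under L-ala and 7.99 ± 0.09 under vehicle in their library means (exact permutation p = 0.0476). Of these 12 markers 3 rose, 0 fell and 9 did not pass, and camera did not pass (adjusted p = 0.111). G6pc (0.02, adjusted p = 0.943) and Pck1 (0.43, adjusted p = 0.125) did not pass. Per1, at 21.4 ± 2.84 FPKM, did not pass either (0.79, adjusted p = 0.0813), but did without vehicle replicate 3 (adjusted p = 0.0244) or vehicle replicate 5 (0.0450). Of 17 core clock genes, 1 rose, 2 fell and 14 did not pass (2 and 3 adjusted over the list alone; camera adjusted p = 0.362). The number that rose was 0 without vehicle replicate 1, 2 or 4 or L-ala replicate 1, 3 or 4, and 2 without vehicle replicate 3 or 5. The number that fell was 0 without vehicle replicate 4 or L-ala replicate 1 or 4, and 1 without vehicle replicate 1, 2 or 3, L-ala replicate 2 or D-ala replicate 1, 2, 3 or 5.

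Vessel markers were lower under L-ala and under D-ala than under vehicle. For L-ala, of 12 tested endothelial markers, 0 rose, 5 fell and 7 did not pass (0 and 7 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 4.67e-05; adjusted p = 0.512 with an estimated correlation), and 3 fell without vehicle replicate 4. Cdh5, the cadherin of endothelial junctions, fell from 4.33 ± 0.605 to 2.78 ± 0.214 FPKM under L-ala (-0.49, SE 0.09, adjusted p = 0.00567). For D-ala, 0 of the 12 markers rose, 3 fell and 9 did not pass (0 and 6 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 9.34e-04; adjusted p = 0.488 with an estimated correlation). The number that fell under D-ala was 1 without vehicle replicate 1, 3, 4 or 5 or D-ala replicate 1, 2 or 3, and 7 without vehicle replicate 2. Library means of the markers were 3.64 ± 0.23 under vehicle, 3.19 ± 0.34 under L-ala and 3.27 ± 0.19 under D-ala on the log2 scale (exact permutation p = 0.0476 for L-ala and 0.0397 for D-ala against vehicle, and 0.667 between the isomers). For L-ala, markers of other cell types passed camera downward as well. They were those of the thick ascending limb (median -0.215, adjusted p = 0.0180), thin limb and inner medulla (-0.24, adjusted p = 0.0132) and macrophages and dendritic cells (-0.223, adjusted p = 0.0307). With an estimated correlation the adjusted p was 0.528, 0.512 and 0.528. Of 11, 11 and 10 tested members, 1, 2 and 1 fell under L-ala and 0 rose. Of 18 interferon response genes, 2 fell, Ifit2 (-0.54, adjusted p = 0.0125) and Rtp4 (-0.57, adjusted p = 0.00229), 0 rose and 16 did not pass (camera adjusted p = 4.92e-04; adjusted p = 0.472 with an estimated correlation); without vehicle replicate 2, 4 fell. Of 24 genes of the mitochondrial respiratory chain, 5 rose, 0 fell and 19 did not pass (14 and 0 adjusted over the list alone; camera adjusted p = 2.84e-06; adjusted p = 0.472 with an estimated correlation). These calls moved with gene length. In the shortest of 5 length bins 361 genes rose and 17 fell under L-ala, in the longest bin 19 rose and 226 fell, and after each library's trend with length was removed 0 chain genes passed. The number of chain genes that rose was 0 without vehicle replicate 2 or 4 or L-ala replicate 1, 3 or 4, 2 without vehicle replicate 1 or D-ala replicate 1 or 3, 3 without D-ala replicate 2 or 5, 11 without vehicle replicate 5 and 14 without L-ala replicate 5.

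In all, 1297 genes changed between L-ala and vehicle, 763 up and 534 down, with 49 up and 12 down by 2-fold or more, and 3590 at an unadjusted p under 0.05. Groups did not overlap in 853 tested genes, 639 of them called; chance gives 0.794%. Rises made up 58.8% of the calls, and 40.7% of 575 calls after quantile normalization. The count rested on single libraries: it was 321 without vehicle replicate 4, 391 without L-ala replicate 4, 626 without L-ala replicate 1, 760 without vehicle replicate 2, 797 without L-ala replicate 3, 802 without vehicle replicate 1 and 2580 without L-ala replicate 5. Of 40 lists 13 passed camera, 8 up and 5 down.

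The stereoisomers differed directly in genes that D-alanine raised, and in NF-kB targets that L-alanine raised. Efna1, a membrane-bound ligand of Eph receptors (GRCm38 chromosome 3, 89271733 to 89281142), was at 120.3 ± 17.3 FPKM under D-ala, 25.1 ± 4.37 under L-ala and 31.8 under vehicle (D-ala against L-ala 2.22, SE 0.11, adjusted p = 8.54e-09). Slc16a6, a carrier of the monocarboxylate family (chromosome 11, 109450855 to 109473598), was at 15.5 ± 1.74 against 2.84 ± 0.475 FPKM (2.10, SE 0.11, adjusted p = 1.12e-08). Slc20a1, a sodium-dependent phosphate carrier, was at 69.4 ± 10.6 against 22.7 ± 3.77 FPKM (1.57, SE 0.16, adjusted p = 5.80e-05). Slc20a1 rose under L-ala too (0.65, adjusted p = 0.0255 against vehicle). Vegfa, the growth factor of blood vessels, was higher under D-ala by a log2 fold change of 0.88 (SE 0.10, adjusted p = 7.14e-05). Irs2, an adaptor of the insulin receptor, was higher by 1.54 (SE 0.24, adjusted p = 0.00165). Nfkbia was lower under D-ala, at 42.7 ± 27.4 against 197 ± 52.3 FPKM (-2.36, SE 0.37, adjusted p = 0.00227), as was Tnfaip3 (-2.30, SE 0.32, adjusted p = 8.60e-04).

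Among core clock genes, 6 of 17 were higher under D-ala than under L-ala, 1 was lower and 10 did not pass (7 and 1 adjusted over the list alone). Bhlhe40 differed by 1.58 (SE 0.15, adjusted p = 1.54e-05), Nfil3 by 1.18 (SE 0.22, adjusted p = 0.00418) and Nr1d2 by -0.32 (SE 0.06, adjusted p = 0.00664). Per1 was not called apart (0.63, 95% interval 0.02 to 1.24, adjusted p = 0.147), and it passed in a fit of only the 10 libraries compared (adjusted p = 0.0273, range over its alternatives 0.0273 to 0.262). The list had a median of -0.00 and a mean of 0.31, so that median and mean differ in sign, and camera, whose direction was up, gave adjusted p = 0.0987 (adjusted p = 0.715 with an estimated correlation). The mean of the list per library was 3.69 ± 0.05 under D-ala and 3.4007 ± 0.07 under L-ala (exact permutation p = 0.00794). The number higher under D-ala was 3 without L-ala replicate 1 or 4 or D-ala replicate 1 or 2.

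G6pc was higher under D-ala than under L-ala, at 458 ± 122 against 271 ± 60.2 FPKM (0.74, SE 0.18, adjusted p = 0.0186), and was the 1 of 18 gluconeogenesis genes to differ; 0 were lower and 17 did not pass (1 and 0 adjusted over the list alone; camera adjusted p = 0.642). Pck1 was not called apart (0.38, 95% interval -0.01 to 0.77, adjusted p = 0.168). It passed without vehicle replicate 2 (adjusted p = 0.0446), and the number of members higher under D-ala was 2 without vehicle replicate 2 or L-ala replicate 4, and the number lower was 1 without L-ala replicate 5. For Fbp1 the interval of the difference was -0.13 to 0.14 (adjusted p = 0.972) and for Dao -0.19 to 0.12 (adjusted p = 0.799), on the log2 scale. Of 21 immediate early genes, 2 were higher under D-ala, 0 were lower and 19 were not past the test (camera adjusted p = 0.745), and the members that differed were Myc (1.56, SE 0.27, adjusted p = 0.00348) and Fosl2 (1.10, SE 0.26, adjusted p = 0.0158). The number lower was 1 without vehicle replicate 1 or L-ala replicate 1, and 2 without L-ala replicate 5. The 95% interval of the difference extended by a median of 0.50 to either side for the immediate early genes and 0.18 for all tested genes, so smaller differences were not resolved.

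Targets of cAMP and CREB were higher under D-ala in 5 of 17 cases, lower in 0 and not past the test in 12 (5 and 0 adjusted over the list alone; camera adjusted p = 0.00178; adjusted p = 0.580 with an estimated correlation). They were higher in 3 cases without L-ala replicate 1, 3 or 4 or D-ala replicate 1, 2 or 3. NF-kB targets were lower under D-ala in 6 of 17 cases, higher in 0 and not past the test in 11 (8 and 0 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 4.60e-04; adjusted p = 0.580 with an estimated correlation); without L-ala replicate 5, 1 was higher. Neutrophil markers moved with these genes, as given above. Chaperones of the heat shock list were lower under D-ala in 9 of 18 cases, higher in 0 and not past the test in 9 (15 and 0 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 2.06e-06; adjusted p = 0.580 with an estimated correlation). Dnajb1, a partner of Hsp70, was at 16.6 ± 1.03 FPKM under D-ala and 31.5 ± 5.56 under L-ala (-0.87, SE 0.13, adjusted p = 0.00101). Hspa8, the constitutive Hsp70, was at 225 ± 18.2 against 342 ± 56.1 FPKM (-0.59, SE 0.13, adjusted p = 0.0107). Slc38a3, a glutamine carrier of the ammonia pathway, rose under D-ala (0.45, SE 0.11, adjusted p = 0.0120) and fell under L-ala (-0.43, SE 0.11, adjusted p = 0.0213). The isomers differed by 0.89 (SE 0.11, adjusted p = 1.27e-04). The fall under L-ala was not past the test without L-ala replicate 4 (adjusted p = 0.0626; range over its alternatives 0.0159 to 0.126).

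**Figure D3:**
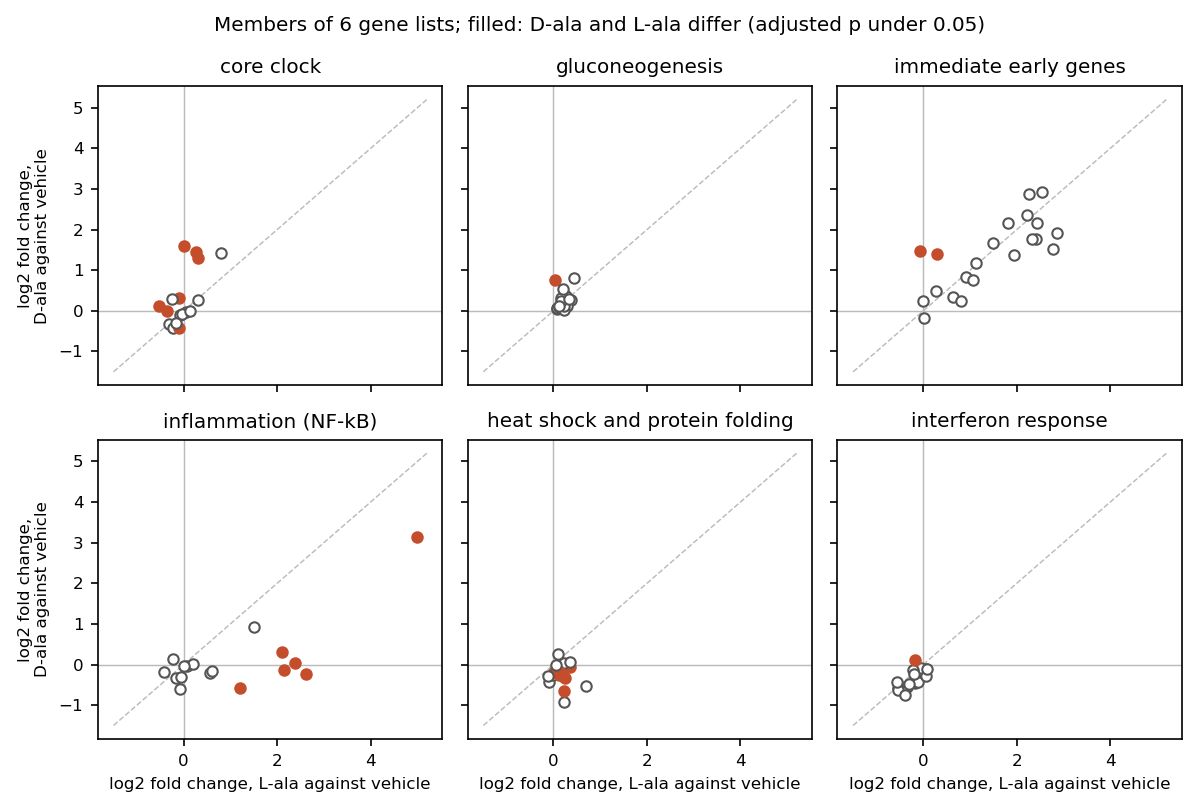
Each point is a tested member of 1 of 6 gene lists, with its log2 fold change for L-ala against vehicle on the x axis and for D-ala against vehicle on the y axis; filled points are genes whose D-ala and L-ala groups differed at an adjusted p under 0.05, and the dashed line marks equal fold changes. Filled points lie above the line in the core clock list (6 genes, and 1 below) and below it in the NF-kB (6) and heat shock (9) lists, and 2 of 21 immediate early genes are filled.

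In all, 1611 genes differed between the isomers, 826 higher and 785 lower under D-ala, with 23 higher and 12 lower by 2-fold or more, and 3632 at an unadjusted p under 0.05. Groups did not overlap in 1073 tested genes, 860 of them called; chance gives 0.794%. These differences also moved with gene length: 38 genes were higher and 320 lower under D-ala in the shortest of 5 bins, and 321 higher and 51 lower in the longest. The count was 770 without L-ala replicate 4, 969 without D-ala replicate 3, 1019 without D-ala replicate 1, 1026 without L-ala replicate 1, 1061 without D-ala replicate 4, 1070 without L-ala replicate 3 and 2761 without L-ala replicate 5. Of 40 lists 6 passed camera, 3 up and 3 down.

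Both isomers raised 175 genes and lowered 155 against the same vehicle libraries, and 4 genes were called in opposite directions, Als2cl (0.24 under D-ala and -0.32 under L-ala), Arrdc3 (0.58 and -0.50), Lama5 (0.45 and -0.29) and Slc38a3; the first 3 of these were chosen after their values were seen. Independent lists would share 49.8 genes that rose and 26.3 that fell. Simulated unchanged groups shared at most 0, but groups without changes leave few calls to share. That 0 does not show how many shared calls the common vehicle libraries add where both groups have real but unrelated changes. Fold changes of D-ala and L-ala correlated across genes, which are not independent replicates, with r = 0.615; unchanged groups simulated against the same vehicle libraries gave a mean r of 0.470 and a range of 0.0734 to 0.755 over 100 simulations. The covariance was 0.0481 against a simulated 0.0135, a difference of 0.0346. With the vehicle libraries split so that the comparisons shared none, the median over 20 choices was r = 0.395 (0.227 to 0.473), the covariance 0.0353, and 35 genes (8 to 76) rose and 17 (1 to 40) fell in both. Each split comparison had fewer vehicle libraries, and 153 to 597 genes rose under D-ala and 10 to 877 under L-ala. The shared counts of the splits therefore cannot be set against the 49.8 and 26.3 of the full comparisons. No number expected from independent lists was worked out for the splits. Among genes that changed the same way against vehicle under both, 300 were not called apart between the isomers.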

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

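The tests of library depth, of shared vehicle libraries and of other splits of the libraries were written down before their results were seen, and all other tests in this part were chosen only after the result was seen. In 99 groups of 5 values tested for a library far from the others, 8 held one, where chance alone gives about 4.95. The genes and measures searched were chosen after the data had been seen.

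Under vehicle, Plk3 was at 47.485 FPKM in replicate 3 and 2.568 to 15.047 in the other libraries. Nfil3 was at 4.692 FPKM in D-ala replicate 4 and 12.893 to 14.002 in the other D-ala libraries. Tnfaip3 was at 4.39 FPKM in vehicle replicate 2 against 1.195 to 2.022 in the others, and at 5.446 FPKM in D-ala replicate 2 against 0.927 to 1.45. Fos was at 62.328 FPKM in L-ala replicate 3 and 13.2 to 22.7 in the other L-ala libraries. In the same library the mean of the immediate early genes was 4.3914 on the log2 scale, against 3.72 to 3.89. Efna1 was at 149.72 FPKM in D-ala replicate 4 and 107 to 118 in the other D-ala libraries. Slc38a2 was at 26.083 FPKM in vehicle replicate 4 and 16.1 to 18.5 in the other vehicle libraries.

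Fold changes of L-ala against vehicle followed gene length, with a Spearman correlation of -0.46 over the tested genes. Once each library's trend with length was removed, 46.49% of the genes called for L-ala stayed called, and the other 694 went from a median size of 0.29 to 0.18 on the log2 scale while their median SE went from 0.0786 to 0.0662. Their calls ended as the fold changes shrank, and much of the size remained, so a length bias between libraries could account for part of these changes. The trend also differed between the groups (exact permutation p = 0.03968), which an effect of L-ala on the RNA would give as well, and the data do not separate the explanations. After all libraries were thinned to the lowest recovered depth, 96.15% of the group difference was left, so unequal read numbers alone did not produce it. Thinning keeps each gene's expected share of the reads. It therefore cannot exclude a bias tied to depth that was already present in the reads.

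NF-kB targets were higher under L-ala than under D-ala in 6 of 17 cases: Nfkbia, Tnfaip3, Cxcl1, Cxcl2, Cxcl10 and Irf1. Length bias was excluded as the whole cause, since 5 of the 6 genes stayed called with the length trend removed. Neutrophils in the tissue stay open: the neutrophil genes S100a8 and S100a9 together gained 16.94 FPKM, 10.98% of the gain of Nfkbia but more than the gain of 2 of the 6 genes, and their ratio to these genes in neutrophils was not measured. A contaminant such as endotoxin given with L-ala could also raise NF-kB targets. Of 18 interferon response genes 0 rose under L-ala, which does not settle the question at 2 h. Cxcl10 and Irf1 are outside that interferon list, and they gained 35.4 and 19.48 FPKM from D-ala to L-ala. A response to L-ala itself was not tested apart from these explanations.

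Immediate early genes rose under both isomers. When the comparisons shared no vehicle library, the lowest median log2 fold change of the list over 20 choices was 0.8478. The rise under both isomers therefore did not need the same vehicle libraries in both comparisons. All these libraries came from the same vehicle group, so the split cannot exclude a vehicle group that was low as a whole. Handling or timing that differed between libraries could raise these genes: the list mean ranged over 0.92 on the log2 scale among the vehicle libraries, 80.56% of the smaller treated difference. That sets a range of single libraries against a difference of group means. The library means did not overlap, at 2.24 to 3.16 under vehicle, 3.72 to 4.39 under L-ala and 3.63 to 4.04 under D-ala. The exact permutation p was 0.00794 for each isomer against vehicle. Handling that differed between the groups would give this as well, so handling and a response to both amino acids stay unresolved.

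For each comparison, 100 splits of the 10 libraries into 5 and 5 were fitted, drawn at random with the real one included. The real split called 1431 genes for D-ala against vehicle, 603 for L-ala against vehicle and 975 for D-ala against L-ala, and in each case 1 split, the real one, called as many. The highest of the others called 4, 7 and 268 genes. The split with 268 set L-ala replicates 1 to 4 and D-ala replicate 2 against L-ala replicate 5 and the other D-ala libraries.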

How the results depend on the processing

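Of 254 calls of named genes, 75 held under every alternative in which the gene was tested. The cutoff of 1.5-fold by itself ended 140 of the 254, since it drops every call with a smaller fold change by definition. With a mean of at least 5 FPKM, 234 of the 271 named gene results were tested. Under alternatives the number of genes changed for D-ala against vehicle, L-ala against vehicle and D-ala against L-ala was 264, 167 and 155 when fold changes were kept only from 1.5 up. For L-ala against vehicle it was 575 with quantile normalization, 2308 with array quality weights, 603 with only the 10 libraries compared and 750 with the length trend removed; for D-ala against L-ala it was 2700 with array quality weights, 975 with only the 10 libraries compared and 996 with the adipocyte covariate. Lists past camera numbered 1, 0 and 0 with an estimated correlation, 7 for L-ala against vehicle with array quality weights and 8 without the 3 libraries of lowest depth, and for D-ala against L-ala 11 with quantile normalization and 10 with no filter. The gluconeogenesis list had an adjusted p of 0.159 for D-ala against vehicle with an estimated correlation and 0.0289 for D-ala against L-ala with quantile normalization, and the core clock list 0.0261 for D-ala against L-ala at a mean of at least 5 FPKM. The correlation of the fold changes of the isomers was 0.395 with the vehicle libraries split. Leaving out 1 library gave 812 to 1592 genes for D-ala against vehicle, 321 to 2580 for L-ala against vehicle and 770 to 2761 for D-ala against L-ala, and 7 to 18 lists for L-ala against vehicle. The causes of these changes were not tested, and counts went up as well as down with fewer libraries. FPKM from 7.55 to 10.9 M reads limit what can be said of genes under 1 FPKM, Arntl among them.

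These results turned direction under an alternative, none of them past the threshold there; values are adjusted p for lists and log2 fold changes for genes, and the cause was not tested. Of them only Aldoa and Slc34a1 and the mitochondrial chain list for L-ala against vehicle and for D-ala against L-ala had passed in the analysis of the text. With fry's directional test, for D-ala against vehicle cell cycle 0.850, and for L-ala against vehicle hypoxia targets 0.996, sodium and water transport 0.857, proximal tubule S3 markers 0.857, sex-linked genes 0.843, and for D-ala against L-ala glucocorticoid targets 0.876. With median-of-ratios scaling, for D-ala against vehicle endoplasmic reticulum stress 0.993, and for L-ala against vehicle proximal tubule S3 markers 0.993, sex-linked genes 0.986, and for D-ala against L-ala glucocorticoid targets 0.955. With quantile normalization, for D-ala against vehicle endoplasmic reticulum stress 0.428, NF-kB 0.899, cell cycle 0.755, mitochondrial respiratory chain 0.442, urothelium markers 0.876, and for L-ala against vehicle Aldoa -0.0256, Fbp1 -0.0209, G6pc -0.1582, Slc34a1 -0.0633, glycolysis 0.558, mTORC1 and lysosome 0.120, PPARalpha and fatty acid oxidation 0.353, endoplasmic reticulum stress 0.790, urate, ammonia and acid-base 0.353, mitochondrial respiratory chain 0.363, proximal tubule S1-S2 markers 0.597, and for D-ala against L-ala Dao 0.0729, mitochondrial respiratory chain 0.803, proximal tubule S1-S2 markers 0.376. With array quality weights, for D-ala against vehicle endoplasmic reticulum stress 0.760, and for L-ala against vehicle G6pc -0.0311, and for D-ala against L-ala proximal tubule S1-S2 markers 0.897. With no filter, for D-ala against vehicle cell cycle 0.923, and for L-ala against vehicle alanine handling 0.747, sodium and water transport 0.881, proximal tubule S3 markers 0.881, and for D-ala against L-ala glucocorticoid targets 0.932, kidney injury 0.984, thick ascending limb markers 0.990. With a mean of at least 5 FPKM, for D-ala against vehicle cholesterol synthesis 0.935, endoplasmic reticulum stress 0.908, NF-kB 0.711, and for L-ala against vehicle PPARalpha and fatty acid oxidation 0.799, podocyte markers 0.703, sex-linked genes 0.643, and for D-ala against L-ala proximal tubule S1-S2 markers 0.956, sex-linked genes 0.941. With only the 10 libraries compared, for L-ala against vehicle proximal tubule S3 markers 0.948, sex-linked genes 0.985. With a pseudocount of 0.1, for D-ala against L-ala glucocorticoid targets 0.991. With a pseudocount of 5, for L-ala against vehicle proximal tubule S3 markers 1, sex-linked genes 0.982. With the length trend removed, for L-ala against vehicle G6pc -0.0035, Per2 0.004, alanine handling 0.906, hypoxia targets 0.872, kidney injury 0.845, sodium and water transport 0.680, proximal tubule S3 markers 0.846, urothelium markers 0.865, sex-linked genes 0.872, and for D-ala against L-ala Dao 0.0231, urothelium markers 0.852. With the GC trend removed, for L-ala against vehicle proximal tubule S3 markers 0.965, sex-linked genes 0.843, and for D-ala against L-ala Fbp1 -0.005, glucocorticoid targets 0.858. With voom on recovered reads, for D-ala against vehicle cell cycle 0.949, and for L-ala against vehicle sodium and water transport 0.986, proximal tubule S3 markers 0.970, sex-linked genes 0.948, and for D-ala against L-ala glucocorticoid targets 0.910. With the 3 libraries of lowest depth left out, for D-ala against vehicle endoplasmic reticulum stress 0.808, cell cycle 0.935, and for L-ala against vehicle G6pc -0.0958, sodium and water transport 0.954, urothelium markers 0.782, and for D-ala against L-ala proximal tubule S1-S2 markers 0.632, thick ascending limb markers 0.744, urothelium markers 0.967. With the adipocyte covariate, for D-ala against L-ala Dao 0.0184, Fbp1 -0.0146, immediate early genes 0.823, glucocorticoid targets 0.625, kidney injury 0.810. Some results turned direction when 1 library was left out, with these ranges over the libraries: for D-ala against vehicle cell cycle 0.691 to 0.996, cholesterol synthesis 0.622 to 0.972, collecting duct principal cell markers 0.369 to 0.996, endoplasmic reticulum stress 0.615 to 0.988, NF-kB 0.299 to 0.982, urothelium markers 0.526 to 0.986. For L-ala against vehicle adipocyte markers 0.361 to 0.848, alanine handling 0.616 to 0.983, G6pc -0.0928 to 0.1025, podocyte markers 0.380 to 0.848, PPARalpha and fatty acid oxidation 0.242 to 0.939, proximal tubule S3 markers 0.409 to 0.993, sex-linked genes 0.592 to 0.9999, sodium and water transport 0.646 to 0.993, urothelium markers 0.618 to 0.979. For D-ala against L-ala Dao -0.0698 to 0.0027, endothelial markers 0.0631 to 0.977, Fbp1 -0.0368 to 0.0502, glucocorticoid targets 0.570 to 0.997, immediate early genes 0.517 to 0.979, kidney injury 0.437 to 0.977, proximal tubule S1-S2 markers 0.517 to 0.995, thick ascending limb markers 0.318 to 0.979, urothelium markers 0.502 to 0.977.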

Other observations

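The test of the clock's phase in this part was chosen only after the result was seen. Some genes of the distal nephron changed under D-ala, and markers of the distal convoluted tubule moved with them. Of 11 such markers, Slc12a3 among them, 3 rose, 0 fell and 8 did not pass (4 and 0 adjusted over the list alone; camera adjusted p = 0.0287; adjusted p = 0.398 with an estimated correlation). Their library means were 4.75 ± 0.14 under D-ala and 4.58 ± 0.04 under vehicle on the log2 scale (exact permutation p = 0.00794). Camera did not pass for them without vehicle replicate 2 (adjusted p = 0.0540) or D-ala replicate 2 (0.1002) or 4 (0.0733), and 1 rose without vehicle replicate 2 or D-ala replicate 2. Markers of the thick ascending limb went the other way and passed camera downward (median -0.11, adjusted p = 0.0291, and 0.618 with an estimated correlation). Of 11 such markers 0 rose, 1 fell and 10 did not pass, and their library means did not pass (exact permutation p = 0.175). Whether the shares of these segments in the samples differed was not tested. Slc12a3, the thiazide-sensitive sodium chloride carrier, rose from 131 ± 15.6 to 184 ± 24.8 FPKM (0.49, SE 0.10, adjusted p = 0.00581), and was higher than under L-ala (0.48, adjusted p = 0.00834). Nedd4l, a ubiquitin ligase that removes the epithelial sodium channel from the membrane, rose (0.29, SE 0.06, adjusted p = 0.00821), as did Scnn1b, a subunit of that channel (0.30, SE 0.07, adjusted p = 0.0135). Aqp2, the vasopressin-regulated water channel, fell from 290 ± 35.2 to 214 ± 19.1 FPKM (-0.43, SE 0.09, adjusted p = 0.00691). Of 27 tested genes of sodium and water transport, 8 rose, 1 fell and 18 did not pass (9 and 2 adjusted over the list alone; camera adjusted p = 0.00961; adjusted p = 0.359 with an estimated correlation). The number that rose was 4 without vehicle replicate 3, 4 or 5 or D-ala replicate 1, and 5 without D-ala replicate 2 or 4. The number that fell was 2 without L-ala replicate 4 or D-ala replicate 4, and camera lost the list after quantile normalization (adjusted p = 0.0573). Slc4a9, an anion exchanger of intercalated cells, rose (0.49, SE 0.08, adjusted p = 0.00124), as did Slc26a4, their chloride and bicarbonate exchanger pendrin (0.27, SE 0.07, adjusted p = 0.0130). Of 12 intercalated cell markers 4 rose, 0 fell and 8 did not pass (6 and 0 adjusted over the list alone; camera adjusted p = 0.00131; adjusted p = 0.159 with an estimated correlation), and 2 rose without vehicle replicate 4 or D-ala replicate 4.

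In the list of urate, ammonia and acid-base genes, 6 of 18 rose under D-ala, 0 fell and 12 did not pass (6 and 0 adjusted over the list alone; camera adjusted p = 0.00262; adjusted p = 0.109 with an estimated correlation). Slc22a6, the organic anion transporter of the proximal tubule, rose from 271 ± 13.9 to 359 ± 30.8 FPKM (0.40, SE 0.06, adjusted p = 8.19e-04), and Car12, a membrane carbonic anhydrase, rose from 73.1 ± 3.91 to 90.4 ± 6.13 FPKM (0.30, SE 0.06, adjusted p = 0.00404). Of 11 markers of the thin limb and inner medulla, 0 rose, 3 fell and 8 did not pass (0 and 5 adjusted over the list alone; camera adjusted p = 0.00117; adjusted p = 0.224 with an estimated correlation), and 5 fell without L-ala replicate 4 or D-ala replicate 4, 1 without vehicle replicate 3 or 5 or D-ala replicate 1 or 2, and 0 without vehicle replicate 4 or D-ala replicate 5. Of 11 targets of the osmotic regulator NFAT5, 1 rose, 3 fell and 7 did not pass (1 and 4 adjusted over the list alone; camera adjusted p = 0.00548; adjusted p = 0.159 with an estimated correlation). The number of these that rose was 0 without any 1 of the vehicle libraries or D-ala replicate 1 or 2. Under L-ala, 1 of the 11 NFAT5 targets rose, 3 fell and 7 did not pass (camera adjusted p = 0.0505). Markers of the thin limb and inner medulla went down under L-ala too, as given above.

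The rise of Per1, Nfil3, Gm129 and Bhlhe40 under D-ala could reflect a shift of the clock's phase. The median log2 fold change of 7 other outputs of the feedback loops was -0.0695, with an SD of 0.30 between them, but 3 of the 7 lay above 0 and 4 below. A phase shift moves genes of different phase in opposite directions, so this test does not decide and the explanation stays open.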
